A study of Drosophila melanogaster with 3 samples.

How the data were processed

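Transcription factor ChIP-seq was performed on transgenic fly embryos of 0 to 24 h that express CG10274 fused to GFP, with chromatin sheared by sonication to 200 to 800 bp and an antibody against GFP, per the labels. The 3 samples are biological replicates 1, 2 and 3 of 1 group by the replicate numbers in the labels, which name 1 transgenic line. Nothing in the labels gives a second group, and the control data set they name was not analysed here. The descriptions beside the lists name, for each replicate and pooled list, 1 further input file besides the alignments, taken to be a control, so the peaks may already be called against it.

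Peak lists came in the narrowPeak format for the dm6 and dm3 builds, per the labels and the descriptions deposited beside them. For each build there was 1 list per replicate and 1 list called on pooled replicates, each meant as input to IDR, and 1 list of peaks that passed IDR, called the combined list here. The authors' peak score (column 7) is a positive number with no fixed range that was not scaled between lists: the highest score was 11952 in replicate 1, 5759 in replicate 2 and 5507 in replicate 3. The −log10 q-value per peak (column 9), as deposited by the authors, reaches a ceiling shared by many peaks (2266 of the 2988 combined peaks), so peaks were ranked by the score. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. Each replicate list holds 30000 entries, described by the authors as peaks and background, so low ranks were not read as binding. All 2988 combined peaks were found in the pooled list and were exactly its 2988 highest-scoring entries. They cover 2950 distinct intervals, since some intervals hold more than 1 summit. Scores give no read counts, so depth per sample is unknown, and all intervals on shares cover the counting of peaks or genes only.

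The dm6 lists were analysed with the Drosophila melanogaster release 6 genome and the BDGP 6.54 annotation of Ensembl release 115. The last combined peak on arm 3R ended at 31977892, within the reference arm of 32079331 bp. Transposable elements were left out of the annotation, which then held 18277 genes on 7 chromosome arms, 13968 of them protein-coding, and 23694 distinct transcription start sites (TSSs). Coordinates were not converted between builds, and the dm3 lists were used only for comparisons that need no annotation. Coordinates are given 1-based.

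Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Replicates were compared on their top 2988 peaks by score, the number of combined peaks, with an overlap of at least 1 bp. Random expectations came from 100 seeded placements of the peaks within their own chromosome. Promoter-proximal means a summit within 500 bp of an annotated TSS. Relative scores divide the score of the best overlapping peak in a replicate by that replicate's median over the 2292 combined peaks present in all 3 replicate lists (medians 112.5, 74.9 and 56.3 in replicates 1, 2 and 3), and a mean ± SD is given only where all 3 lists have the peak. Chromosome arms were tested with two-sided exact binomial tests against arm length. Gene lists were tested with two-sided Fisher's exact tests, with all other protein-coding genes as background, or all other genes for tRNA genes. Motifs were tested at summits ± 50 bp against flanks at 500 bp with an exact McNemar test, in which 1 flank per peak was drawn by a seeded coin. The printed flank share is the mean of both flanks. Benjamini-Hochberg adjustment was applied over the 7 arms, the 21 lists and the 12 motifs, with a threshold of 0.05. Scores of promoter and other peaks were compared with 100000 permutations. Shares have 95% Wilson intervals, and for a count of 0 the limit is 3 counts of the total.

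The lists held cytosolic and mitochondrial ribosomal proteins, proteasome subunits, aminoacyl-tRNA synthetases, translation initiation factors, respiratory chain, DNA replication and cell cycle, histones, Hox, segmentation, proneural and Notch pathway, architectural proteins, ZAD zinc-finger proteins, Polycomb and trithorax group, heat shock, muscle, neuronal, cuticle, germline and piRNA, odorant and gustatory receptors, and tRNA genes. Lists, motifs, tests and the rule for named genes were fixed before the data were examined, apart from the later choices given below. Symbols that did not match the annotation were looked up among older symbols in a RefSeq gene table, and 5 of them stayed unmatched. Named are CG10274 and peaks within 5000 bp of it, the genes of the 20 highest-scoring peaks within 500 bp of a protein-coding TSS that the top peaks of all 3 replicates support, the 5 highest-scoring peaks with no TSS within 2000 bp, and the highest-scoring members of each list, up to 4 where the list passed and up to 2 otherwise.

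Chosen after the data were seen were a weight matrix of 16 positions, the comparison of summit positions at ribosomal protein genes, the check of tRNA genes with unique flanks, the counts per annotated feature, random placements matched on AT content, and the first 8-mer kept without a new search when a replicate was left out. So were the test of combined housekeeping gene classes, the reading of ribosomal protein genes per replicate, and the test of divergent gene pairs. The matrix was fitted by expectation maximisation to the 276 peaks of the top 500 that lie on 2L, 3L and X, started from the first 8-mer of the search, and its score limit was set so that 5% of flank windows on those arms pass. AT-matched placements drew positions on the same chromosome whose AT content fell in the same bin of 5 percentage points.

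The procedures were tested on simulated data. The promoter test called 1 of 20 randomly placed peak sets and 10 of 10 sets with a planted excess. The 8-mer search ranked an 8-mer planted in 4% of windows first in 5 of 5 runs. That share is higher than the 2.14% of held-out summits with the first 8-mer of the real search. The simulated centre windows were taken away from the summits, so the richness of summits in A and T was not simulated. Random gene lists had an unadjusted p under 0.05 in 9 of 200 draws, and lists enriched by design in 200 of 200. Alternatives covered the number of top peaks, the overlap required, the TSS window, the annotation and background used, the stronger 1494 peaks alone, the dm3 lists, and leaving out each replicate. For tests on the combined list, leaving out a replicate meant keeping the combined peaks that a top peak of each of the other 2 replicates overlaps, which were 1796, 1611 and 1991 peaks without replicates 1, 2 and 3. The combined list itself was made from all 3.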

Results

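Chromatin bound by a GFP-tagged copy of the fly protein CG10274 was recovered with an antibody against GFP from whole Drosophila melanogaster embryos of mixed sex, collected over 0 to 24 h after egg laying, and sequenced (ChIP-seq, which reads the DNA that comes down with a protein). CG10274 (FBgn0035690, arm 3L, 6178677 to 6181829, minus strand) has an annotated protein of 863 amino acids with 13 matches to the C2H2 zinc-finger pattern, a fold that binds DNA in many transcription factors. The samples were 3 biological replicates of 1 group. No other group was compared, so the comparisons are between replicates, between genomic features, and between gene groups. A control data set named in the labels was not analysed here. Each replicate came with a ranked list of 30000 candidate peaks, and the replicates together with a pooled list of 30000 and a combined list of 2988 peaks that passed the authors' test of agreement in rank (the irreproducible discovery rate, IDR). Read totals are not part of these lists, so the depth of each replicate is unknown here. The peak score of each list is the authors' own. It ranks and filters peaks here, and is compared between replicates and between promoter and other peaks. For a named peak the relative score is given, which is its score in a replicate divided by the median score of combined peaks in that replicate, as mean ± SD over replicates. All coordinates are on dm6.

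The first comparison asked which sites the 3 replicates shared. The strongest shared peak at the promoter of a protein-coding gene covered the start of Chro, which encodes the chromodomain protein Chromator of chromosome interbands, and stood at 93.7 ± 15.1 times the median combined peak (SD, n = 3). Peaks at MFS18 (42.0 ± 12.6), at CG5098 (40.7 ± 6.32), at Pgm1 (40.7 ± 12.8), which encodes phosphoglucomutase, and at PNPase (38.8 ± 6.63), which encodes polynucleotide phosphorylase, followed. The peak at CG10274 itself was much weaker. It covered 6181862 to 6182265 on arm 3L, with its summit 235 bp upstream of the CG10274 TSS (position -235), and ranked 1338 of 2988. Replicates 1 and 2 had it among their top 2988 peaks, at relative scores of 0.783 and 1.31, and replicate 3 listed no overlapping peak. A second peak within 5000 bp, at 6185038 to 6185244 near the TSS of CG43293, ranked 597 and was likewise absent from replicate 3's list.

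Among the top 2988 peaks of each replicate, 61.8% ± 6.57 (SD, n = 3 pairs) overlapped a top peak of the other replicate by at least 1 bp. Replicates 1 and 2 shared 68.2%, replicates 2 and 3 shared 62.1%, and replicates 1 and 3 shared 55.1%. Random placement of the peaks within their chromosomes gave a mean of 1.70% and at most 2.41% in 100 draws. The one-sided permutation p of each pair was 0.0099, the smallest that 100 draws can give. With the top 10000 peaks of each replicate the mean overlap was 39.6%. Across combined peaks, the Spearman correlation of peak score between replicates averaged 0.723 ± 0.0785 (SD, n = 3 pairs). It was 0.644 for replicates 1 and 2 (2902 peaks), 0.724 for 1 and 3 (2299 peaks), and 0.801 for 2 and 3 (2343 peaks). Combined peaks without an overlapping peak in both lists of a pair were left out, so the pairs cover different peaks and their order is not a ranking of agreement. These correlations are across peaks, which are not independent replicates, so no p is given.

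Replicate 1 overlapped 78.8% of the combined peaks with its own top peaks (95% Wilson interval 77.3 to 80.2), replicate 2 overlapped 83.4% (82.0 to 84.7), and replicate 3 overlapped 66.2% (64.5 to 67.9). All 3 replicates overlapped 1504 combined peaks, which is 50.3% (48.5 to 52.1), while 58 combined peaks had no support among the top peaks of any replicate. Support fell with the peak score, in part by construction. The combined peaks are the 2988 highest of the list pooled from the same replicates, and each replicate was cut at the same 2988. Combined peaks near that limit can thus easily fall below it in a replicate. In the 299 strongest peaks, 95.7% (92.7 to 97.4) were supported by all 3 replicates, and in the 298 weakest 6.04% (3.85 to 9.34). Raising the lists to the top 10000 peaks of each replicate lifted the supported share from 50.3% to 71.7%, and asking for a reciprocal overlap of 50% lowered it to 30.7%.

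**Figure D1:**
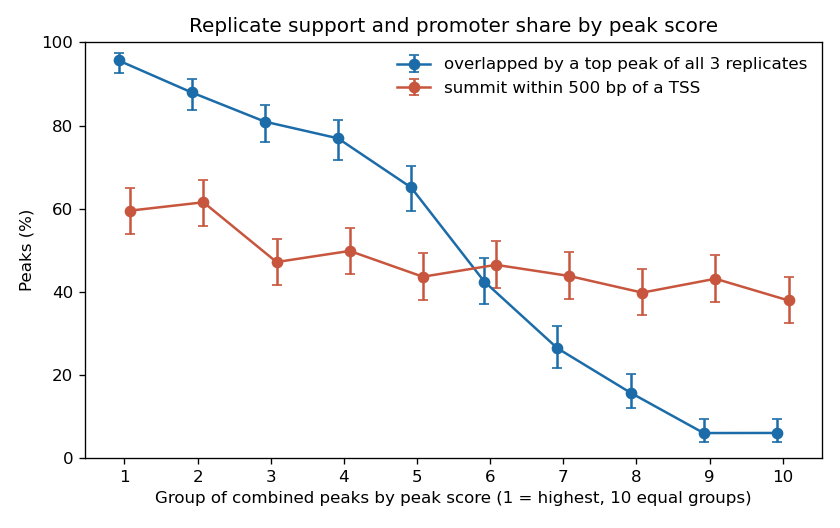
Share of combined peaks (%) in 10 equal groups by peak score, from the highest (1) to the lowest (10), with bars for 95% Wilson intervals. Support in all 3 replicates falls from 95.7% to 6.04%, while the share of summits within 500 bp of a TSS goes from 59.5% to 37.9%.

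The second comparison asked where along genes the protein was found. The 20 strongest peaks with a summit within 500 bp of the TSS of a protein-coding gene and support in all 3 replicates lay at genes of many kinds. Enzymes of metabolism were among them, such as Pgm1, Pgk (phosphoglycerate kinase, 18.8 ± 3.60, n = 3), Fmo-2 (a flavin monooxygenase, 32.1 ± 11.7, n = 3), Mcad (medium-chain acyl-CoA dehydrogenase, 14.9 ± 7.72, n = 3), Jheh1 (juvenile hormone epoxide hydrolase, 15.7 ± 3.98, n = 3) and the cytochrome P450 gene Cyp317a1 (14.7 ± 8.76, n = 3). Signalling genes included the MAP kinase gene p38a (17.2 ± 10.3, n = 3), the kinase gene fray (17.4 ± 5.18, n = 3) and ced-6 (18.6 ± 9.76, n = 3), an adaptor for the engulfment of dying cells. The BTB domain gene lolal stood at 27.6 ± 7.47 (n = 3) and tsu, an exon junction complex gene, at 15.98 ± 5.26 (n = 3). The rest were MFS18, Chro, CG5098, PNPase, CG8188 (32.0 ± 6.48, n = 3), CG1607 (25.1 ± 5.33, n = 3), CG9743 (19.5 ± 6.30, n = 3) and Snx21 (17.9 ± 5.95, n = 3). The interval at ced-6 held 2 of the 20 summits, so 19 genes are named.

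The Chro peak ran from 22878375 to 22879486 on arm 3L, with its summit at 22878895, 89 bp inside the transcribed region of Chro (22873702 to 22878984, minus strand). At Pgm1 (arm 3L, 16126018 to 16128531, minus strand) the peak at 16128215 to 16129215 had its summit upstream of the gene, at -179 bp from the TSS. For MFS18 (arm 2L, 4446670 to 4448635, minus strand) the peak at 4448202 to 4449047 had its summit at -56 bp. For lolal (arm 2R, 18154095 to 18158192, minus strand) the peak at 18156490 to 18157228 had its summit 3 bp from an alternative TSS within the gene. The Pgk peak, at 2750092 to 2750816 on arm 2L, also lay inside its gene (2746880 to 2753068, minus strand), at -254 bp from an internal TSS.

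Of the 2988 combined summits, 1413 lay within 500 bp of an annotated TSS, which is 47.3% (95% Wilson interval 45.5 to 49.1). Random placements within chromosomes gave 13.6% ± 0.610 (SD over 100 draws), so promoters held 3.47 times as many summits, and the one-sided permutation p was 0.0099, the smallest possible. In the replicates' own top peaks the share was 50.5%, 45.2% and 35.4% in replicates 1, 2 and 3, a mean of 43.7% ± 7.64 (SD, n = 3). Weaker pooled peaks that overlap no combined peak lay at promoters in 23.3% of cases (6157 of 26415). Outside promoters, 1129 summits were intronic, which is 37.8% of all 2988 (36.1 to 39.5), against 39.5% at random. Intergenic summits numbered 363, or 12.1% of all 2988 (11.03 to 13.4), against 27.2%. Promoters were counted first and took more of the combined summits than of the random placements, which leaves less for every other feature. Shares among summits outside promoters alone were not compared with random placements. Coding exons outside promoters held 15 summits, or 0.502% (0.304 to 0.827), against 13.8% at random with a lowest draw of 11.98%. That share differed between replicates, with 0.502%, 0.770% and 3.88% in the top peaks of replicates 1, 2 and 3, each below the lowest of its 100 random draws. Annotated 3' UTRs held 0.569% (0.356 to 0.909) of summits against 4.43% at random.

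**Figure D2:**
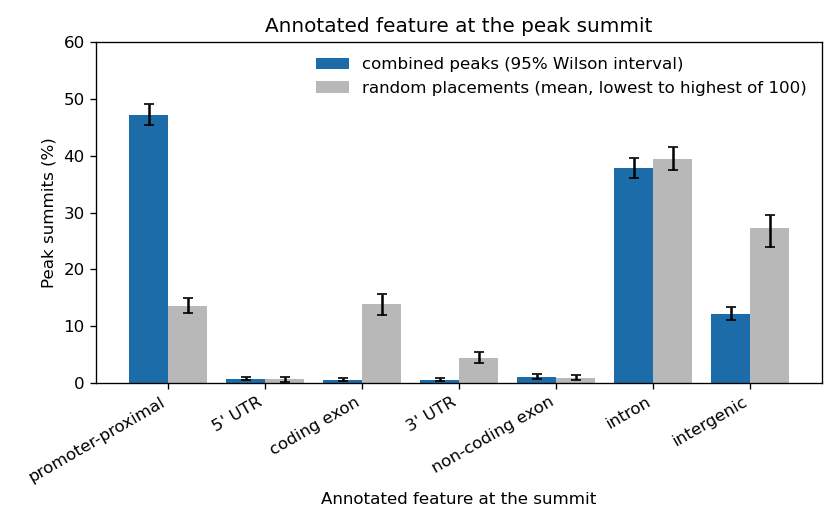
Share of combined peak summits (%) by annotated feature, each summit counted once and promoters first, with 95% Wilson intervals (blue), beside 100 random placements within chromosomes (grey, mean with lowest and highest draw). Promoter-proximal summits make up 47.3% against 13.6%, and coding exons 0.502% against 13.8%.

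The 5 highest of the 828 peaks with no TSS within 2000 bp were at chinmo, crp, Mnt, ftz-f1 and Myc. The peak near chinmo, a BTB zinc-finger gene of neuronal temporal identity, covered 1638422 to 1639135 on arm 2L in intergenic sequence and stood at 32.4 ± 14.4 times the median (SD, n = 3). Its summit was at -12405 bp from the nearest chinmo TSS, and it ranked 6 among all combined peaks. Introns held the peaks of crp (arm 2L, 16279524 to 16280262, 13.9 ± 4.82, n = 3), Mnt (arm X, 3677654 to 3678379, 8.87 ± 5.56, n = 3) and ftz-f1 (arm 3L, 18791408 to 18792107, 8.21 ± 3.66, n = 3), the last a nuclear receptor gene. The peak nearest Myc (arm X, 3360286 to 3360901, 7.85 ± 2.84, n = 3) was intergenic, at -12584 bp. The 5 peaks had support in all 3 replicates.

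Promoter peaks scored somewhat higher than the others. Their median score was 1.17-fold that of other combined peaks (230.5 against 197.2, permutation p = 1e-05, the smallest possible, two-sided). Median scores were also higher at promoters in each of the 3 replicates, by 1.15-fold in replicate 1, 1.11-fold in replicate 2 and 1.27-fold in replicate 3, with permutation p of 1e-05, 4e-05 and 1e-05. Peaks are not independent replicates. The replicate medians cover only combined peaks with a peak in that replicate's list, in replicate 3 1035 promoter and 1316 other peaks. The combined list was made from the same replicates, so the shared direction in 3 of 3 is no independent check.

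The third comparison asked how the peaks were spread over chromosomes. The small chromosome 4 held 10 combined peaks where its length would give 29.3, a ratio of 0.341 (exact binomial test, adjusted p = 0.000283). The X chromosome held 577 peaks against 511.4 expected, a ratio of 1.13 (exact binomial test, adjusted p = 0.00402). The Y chromosome held 0 peaks against 79.7 expected (exact binomial test, adjusted p = 1.53e-34). The embryos were of mixed sex, and how well reads can be placed on the Y was not examined. Expectations from length, or from gene number as below, allow for neither, so the tests on the Y cannot show a lack of binding there. Arms 2L, 2R, 3L and 3R held 543, 552, 607 and 699 peaks, at ratios of 1.06, 1.00, 0.994 and 1.00, and did not pass. With the expectation taken from gene number, 2L and 2R passed as lower too, at ratios of 0.920 and 0.900, and the ratio on X was 1.25. By gene number, chromosome 4 was at 0.518 of its expected 19.3 peaks (exact binomial test, adjusted p = 0.0413) and the Y expectation was 18.5 (adjusted p = 5.43e-08). In the replicates' own top peaks the ratio on chromosome 4 was 0.319 ± 0.0789 (SD, n = 3) and that on X 1.05 ± 0.116 (SD, n = 3). The X excess in single replicates was thus within their spread from 1, at 1.01, 1.18 and 0.954 in replicates 1, 2 and 3, whereas combined peaks supported by both replicates 1 and 3 gave 1.19.

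The fourth comparison asked which of 21 gene groups carried peaks at their promoters. Cytosolic ribosomal protein genes stood out, with a summit within 500 bp of a TSS at 61 of 86 genes (70.9%, 95% Wilson interval 60.6 to 79.5), against 1486 of 13882 other protein-coding genes (10.7%). The odds ratio was 20.4 (Fisher's exact test, adjusted p = 7.01e-38). In the replicates' own top peaks, 66.3%, 69.8% and 45.3% of these genes had a peak in replicates 1, 2 and 3, a mean of 60.5% ± 13.2 (SD, n = 3). Keeping only combined peaks supported by both other replicates, the share was 40.7% without replicate 1, 38.4% without replicate 2 and 61.6% without replicate 3, at odds ratios of 10.6, 10.5 and 20.02, and the call was kept. The highest-scoring members were RpS27 (4.43 ± 0.950, n = 3), RpL7 (3.77 ± 0.928, n = 3), RpS28b (2.35 ± 0.387, n = 3) and RpS10b (2.34 ± 0.325, n = 3). They were far from the strongest peaks of the list. The peaks at ribosomal protein genes ranked from 132 to 2981, with 2 of 62 among the first 300.

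Summits at ribosomal protein genes sat close to the TSS. Their median position was -19 bp (quartiles -37.5 and -6.25), whereas the 1254 promoter peaks of other protein-coding genes had a median of -132 bp (quartiles -249 and -38, two-sided permutation p = 1e-05, the smallest possible; this test was chosen after the data were seen). At RpS27 (arm 3R, 25245955 to 25247514, minus strand) the peak covered 25247364 to 25247662 with its summit 5 bp inside the gene. At RpL7 (arm 2L, 10201004 to 10202321, plus strand) it covered 10200893 to 10201172 with the summit 29 bp inside. The summits of RpS28b and RpS10b, both on X, lay at -22 and -21 bp.

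**Figure D3:**
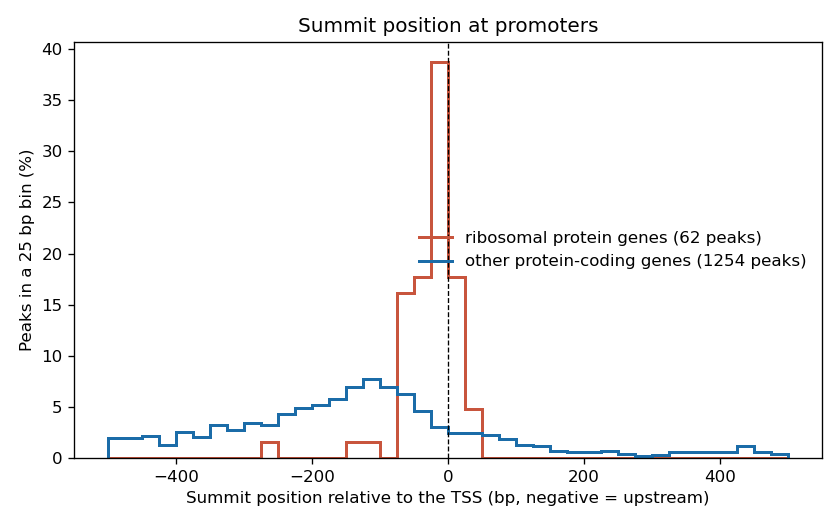
Position of combined peak summits relative to the nearest protein-coding TSS (bp, negative is upstream) in bins of 25 bp, as percent of the 62 peaks at ribosomal protein genes (red) and of the 1254 at other protein-coding genes (blue). The bin just upstream of the TSS holds 38.7% of the former and 3.03% of the latter.

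Lower shares than in other genes were found in 4 groups. Replication-dependent histone genes had 0 of 111 members with a peak, which allows up to 2.70% (Fisher's exact test, adjusted p = 2.35e-05). Those genes lie in near-identical repeats, which limits the mapping of reads to single copies. Cuticle protein genes had 0 of 120, which allows up to 2.50% (Fisher's exact test, adjusted p = 8.47e-06), and odorant and gustatory receptor genes had 0 of 119, which allows up to 2.52% (adjusted p = 8.47e-06). With a TSS window of 1000 bp the receptor share was 1.68%, still called. Transfer RNA genes had 8 of 295 (2.71%, 1.38 to 5.26) against 9.53% of all other genes (odds ratio 0.265, Fisher's exact test, adjusted p = 3.22e-05). The share was 2.53% (7 of 277) among tRNA genes whose flanking sequence occurs once in the genome, a check added after the data were seen. It was 0.339% without replicate 1 or 2, 1.69% without replicate 3, 1.02% with a TSS window of 250 bp, in the stronger 1494 peaks or with only the nearest gene counted, and 4.75% with a window of 1000 bp, and the call was kept in each. Of the 4 tRNA genes with the highest-scoring peak, tRNA:Phe-GAA-1-2 (1.16 ± 0.160, n = 3) had its summit within the gene RpL17, and tRNA:Tyr-GTA-1-8 within CG8036. The other 2 were tRNA:Leu-TAA-2-1 (0.733 ± 0.169, n = 3) and tRNA:Trp-CCA-2-2.

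The other 16 groups did not pass. Genes of Polycomb and trithorax group proteins, which keep gene states through development, had a peak at 7 of 30 (23.3%, 11.8 to 40.9, Fisher's exact test, adjusted p = 0.147), with ph-p (6.66 ± 2.39, n = 3) and brm (2.77 ± 0.762, n = 3) highest. Genes of architectural and insulator proteins had a peak at 6 of 26 (23.1%, 11.03 to 42.1, Fisher's exact test, adjusted p = 0.182), with Chro and Cp190 (2.48 ± 0.143, n = 3) highest. Other gene classes of protein synthesis lay nearer the background than the cytosolic ribosomal proteins. Translation initiation factor genes had 8 of 44 (eIF6 at 5.23 ± 0.595 and eIF4EHP at 3.18 ± 0.376, n = 3), aminoacyl-tRNA synthetase genes 6 of 35 (LeuRS-m at 6.65 ± 1.23 and SerRS at 0.914 ± 0.0806, n = 3), and mitochondrial ribosomal protein genes 10 of 73 (mRpS23, at rank 109, and mRpS10 at 4.25 ± 0.301, n = 3). Respiratory chain genes had 6 of 78, with ND-ASHI (2.39 ± 0.318, n = 3) and ND-MWFE (1.13 ± 0.382, n = 3), and proteasome genes 2 of 48, Rpn5 (1.07 ± 0.214, n = 3) and Rpn3.

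Developmental groups did not pass either. Neuronal genes had 4 of 32, led by Nrx-1 (8.72 ± 3.48, n = 3), a synaptic adhesion gene, and elav (2.73 ± 0.240, n = 3). Muscle genes had 6 of 33, led by Msp300 (2.06 ± 0.187, n = 3) and sls (1.27 ± 0.191, n = 3). Proneural and Notch pathway genes had 5 of 27, led by E(spl)m3-HLH (1.97 ± 0.145, n = 3) and E(spl)m7-HLH (0.997 ± 0.201, n = 3). Segmentation genes had 1 of 26, bcd, and Hox genes 0 of 8, which allows up to 37.5%. Germline and piRNA pathway genes had 2 of 37, bgcn (1.99 ± 0.344, n = 3) and papi. Heat shock genes had 5 of 26, led by Hsp83 (2.71 ± 1.06, n = 3) and Hsp27 (2.50 ± 0.674, n = 3). Genes of DNA replication and the cell cycle had 6 of 36, led by Dp (1.91 ± 0.391, n = 3) and CycE, and ZAD zinc-finger genes had 4 of 24, led by CG4820 and trem (0.818 ± 0.229, n = 3). The adjusted p of each group given here or just above without one was 0.379 or more (Fisher's exact test). The peaks of mRpS23, Rpn3, bcd, papi, CycE and CG4820, given without a relative score, lacked an overlapping peak in the list of at least 1 replicate. Several peaks named for a list lay nearer the TSS of another protein-coding gene, those of brm (Arl1), Cp190 (CG4338), eIF4EHP (CG18428), mRpS23 (CenG1A), mRpS10 (Art3), ND-ASHI (Fum1), ND-MWFE (TppII), Rpn5 (Hat1) and CG4820 (RpS25). With only the nearest gene counted, the share was 13.3% for Polycomb and trithorax group genes, 11.5% for architectural protein genes, 8.33% for ZAD genes, 6.85% for mitochondrial ribosomal protein genes, 9.09% for translation initiation factor genes, 2.56% for respiratory chain genes and 2.08% for proteasome genes, while cytosolic ribosomal protein genes stayed at 70.9%.

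The shares of several groups that did not pass moved with the replicates kept, and none of the 16 passed under any alternative. The share of other genes also falls with fewer peaks or with only the nearest gene counted, so a lower share alone does not show weaker enrichment. Odds ratios for Polycomb and trithorax group genes were 2.98, 2.51 and 1.83 without replicates 1, 2 and 3, against 2.45 in full. Those for DNA replication and cell cycle genes were 0.872, 0.465 and 1.92, against 1.61. Among combined peaks supported without replicates 1, 2 and 3 in turn, which are fewer, the share was 5.56%, 2.78% and 13.9% for DNA replication and cell cycle genes, and 7.41%, 7.41% and 11.1% for proneural and Notch pathway genes. It was 15.4%, 7.69% and 15.4% for architectural protein genes, 16.7%, 13.3% and 13.3% for Polycomb and trithorax group genes, and 8.33%, 8.33% and 12.5% for ZAD genes. Translation initiation factor genes stood at 9.09%, 9.09% and 11.4%, mitochondrial ribosomal protein genes at 8.22%, 8.22% and 10.96%, respiratory chain genes at 2.56%, 2.56% and 3.85%, and proteasome genes at 2.08%, 2.08% and 4.17%. Heat shock genes stood at 11.5%, 11.5% and 15.4%, germline and piRNA pathway genes at 2.70%, 2.70% and 5.41%, and segmentation genes at 3.85%, 0 and 0. The stronger 1494 peaks, also fewer, gave 10% for Polycomb and trithorax group genes, 7.41% for proneural and Notch pathway genes and 11.5% for heat shock genes. They gave 4.17% for ZAD genes and 6.06% for muscle genes, and the latter value was the same with a TSS window of 250 bp.

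**Figure D4:**
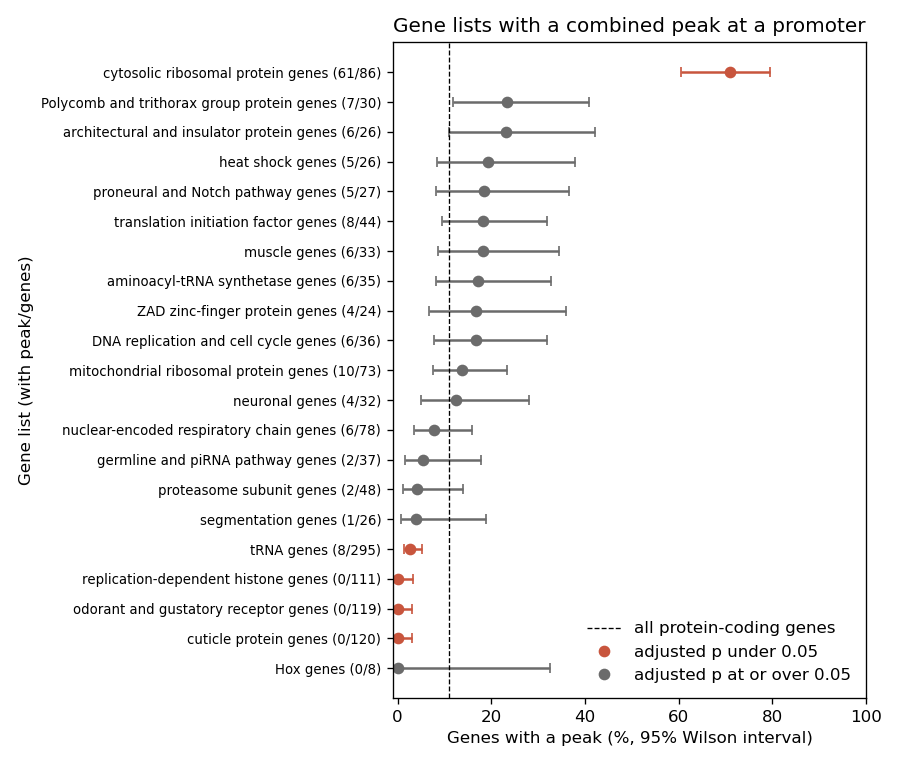
Share of the genes of each list (%) with a combined peak summit within 500 bp of a TSS, with 95% Wilson intervals, beside the share of all protein-coding genes (dashed, 11.1%). Cytosolic ribosomal protein genes stand at 70.9%, and tRNA, histone, receptor and cuticle genes at or below 2.71%.

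The fifth comparison asked which sequences lay under the summits. Windows of 50 bp to either side of the summit were compared with windows centred 500 bp away. The sequence TATAAA of the TATA box was found at 19.9% of summits (95% Wilson interval 18.5 to 21.4) and in 11.1% of flanks (exact McNemar test, adjusted p = 1.59e-24). The summits were rich in A and T, at 63.8% ± 9.60 (SD over 2988 peaks) against 56.9% in flanks. Flanks were not matched on this, so a higher share of A and T rich words at summits cannot be told apart from base composition. The element GTATWTTT, known as Motif 6 of housekeeping promoters, was higher at summits (3.65% against 2.19%, exact McNemar test, adjusted p = 0.000513), as were TATCGATA, the DRE bound by DREF (1.24% against 0.351%, exact McNemar test, adjusted p = 0.00531), and the CTCF site (0.736% against 0.251%, exact McNemar test, adjusted p = 0.0322). The GAGA element was lower at summits, at 0.937% against 3.40% (exact McNemar test, adjusted p = 1.67e-11), and so was the E-box CAGCTG, at 3.68% against 4.97% (exact McNemar test, adjusted p = 0.0198). Both words, GAGAGAG and CAGCTG, hold more G and C than A and T. How far base composition lowers them at summits was not tested. The BEAF-32 core, Motif 1, the Su(Hw) site, the Zelda site, the GATA site and the initiator did not pass, with 13.3%, 0.402%, 1.94%, 0.636%, 1.71% and 8.43% of summits. Some of them passed under alternatives. The Su(Hw) site was higher at summits with windows of 100 bp to either side (adjusted p = 0.0171), without replicate 2 (0.0381) and without replicate 3 (0.00409, exact McNemar tests). The BEAF-32 core was higher with those windows (adjusted p = 0.0035) and without replicate 3 (0.0168), and Motif 1 without replicate 2 (0.0381, exact McNemar tests). Wider windows raise all shares by construction.

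Against promoters without a peak, windows at promoter peaks gave other directions for several elements. The control windows were centred on the TSS and the peak windows on summits, whose median position was -132 bp outside ribosomal protein genes. A lower share of elements placed at the TSS, such as the initiator, can follow from that placement alone. It does not set promoters with a peak apart from those without. The DRE was found at 2.41% of promoter summits and 3.87% of the 8597 control TSSs (Fisher's exact test, adjusted p = 0.0116), and the TATA box at 20.4% and 19.5% (adjusted p = 0.597). The direction turned for GAGA, at 1.20% and 0.872%, which did not pass (adjusted p = 0.343, Fisher's exact test). The BEAF-32 core (15.9% and 22.1%), Motif 1 (0.778% and 2.94%) and the initiator (8.21% and 23.4%) were lower at promoter peaks, and the Su(Hw) site was higher (1.77% and 0.744%), each with an adjusted p of 0.00138 or less by Fisher's exact test. Motif 6 was at 3.75% of both (adjusted p = 1), and the CTCF site, at 0.495% and 0.186%, did not pass there either (adjusted p = 0.0591, Fisher's exact test). The E-box was lower at promoter peaks there too (4.32% and 7.14%, Fisher's exact test, adjusted p = 0.000137). Against flanks, on the fewer peaks left without 1 replicate, some calls were lost. The CTCF site stood at 0.947% against 0.306%, 0.807% against 0.372% and 0.703% against 0.301% without replicates 1, 2 and 3, with adjusted p of 0.0923, 0.0736 and 0.173 (exact McNemar test). Without replicate 1, the DRE stood at 1.06% against 0.362% (adjusted p = 0.174) and the E-box at 3.29% against 5.29% (adjusted p = 0.0923, exact McNemar tests). The E-box call was also lost in the stronger 1494 peaks (3.48% against 5.15%, adjusted p = 0.0548) and with windows of 100 bp to either side (8.33% against 9.64%, adjusted p = 0.170, exact McNemar tests). The GAGA share against flanks was 0.501% without replicate 1 and stayed called.

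A search of all 8-mers on arms 2L, 3L and X put ATACCCTA (reverse complement TAGGGTAT) first, with 35 peaks that had it at the summit alone and 3 in the flank alone. On the held-out arms 2R, 3R and 4, it was found at 2.14% of 1261 summits (95% Wilson interval 1.48 to 3.10) and in 0.0793% of flanks (exact McNemar test, p = 1.62e-06). The A and T rich words AAAAATAT (99 peaks against 38), TAAATTAA and TATAAAAA ranked 2nd, 4th and 5th, with Bonferroni-adjusted p of 0.0061, 0.0154 and 0.024 in the search (exact McNemar tests). ACCCTACA, which shares ACCCTA with the first word, ranked 3rd, with 23 peaks against 0. When the arms of search and test were swapped, GTAGGGTA came first and was found at 1.39% of summits against 0.232% of flanks (exact McNemar test, p = 8.8e-05). In the stronger 1494 peaks, the share of ATACCCTA on held-out arms was 2.95% against 0 in flanks. Other settings put other words first. Windows of 100 bp to either side gave CACTGTGC (3.57% against 0.833%, exact McNemar test, p = 1.31e-05), and a search of 7-mers gave the A and T rich TTTAAAA (11.3% against 4.08%, exact McNemar test, p = 4.11e-11). Among combined peaks supported by replicates 2 and 3, that is without replicate 1, the search put the A and T rich GTTTAAAA first, which did not pass on held-out arms (1.45% against 0.724%, exact McNemar test, p = 0.0574). On the held-out arms of that same set, ATACCCTA itself was found at 2.63% of 760 summits against 0.132% of flanks (exact McNemar test, p = 2.1e-05), a test chosen after the data were seen.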

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

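Tests with the weight matrix, with AT-matched placements and of housekeeping gene classes, and the reading of ribosomal protein genes per replicate, were chosen after the peaks had been examined, although the outcomes required of the matrix and AT-matched tests were set before those results were seen. The design has 1 group, so no biological explanation that sets samples apart was tested. The excess of peaks on X was first among the patterns to be weighed and was set aside for the coding exons after its tests were seen: the ratio to the length expectation was 0.954 in the lowest replicate, which met the outcome set for a single-replicate source, but 1.21, 1.19 and 1.14 in combined peaks supported without replicates 1, 2 and 3, and 1.25 against gene number. Its source stays open, and both expectations include the empty Y chromosome, which raises the ratio on X.

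A small difference appeared in pooled peaks that did not pass IDR, which the motif comparison leaves aside. On held-out arms, the weight matrix matched 4.95% of 11487 such summits (95% Wilson interval 4.57 to 5.37) and 3.64% of their flanks (exact McNemar test, p = 6.12e-06). The summit share was no higher than the 5% of flank windows that the score limit was set to pass on the fitting arms. That limit was set on other arms, so it does not cancel the difference from their own flanks. Those flanks were not matched on base composition, so whether the difference reflects the sequence stays undecided.

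Cytosolic ribosomal protein genes had peaks at 70.9% of their promoters. Other housekeeping lists did not reach that share. Mitochondrial ribosomal protein, proteasome and respiratory chain genes together had a peak at 9.05% (18 of 199, 5.80 to 13.8). These lists were combined after their shares were known, so that outcome is no independent test. Translation initiation factor genes (18.2%, 9.51 to 32.0) and aminoacyl-tRNA synthetase genes (17.1%, 8.10 to 32.7) were left out and were higher. Their intervals also lay below 60.6%, the lower end for cytosolic ribosomal protein genes. The share of the latter was 40.7%, 38.4% and 61.6% without replicates 1, 2 and 3. A single replicate does not account for it, because the lowest odds ratio over the 3 replicates' own top peaks was 9.95, in replicate 3 (Fisher's exact test, p = 7.58e-21). The matrix describes a minority of the strongest peaks. On held-out arms it matched 14.1% of the 142 summits among the first 300, against 4.23% of flanks (exact McNemar test, p = 0.00661). Over all 1261 held-out summits it matched 7.22% against 4.64% (p = 0.00954, exact McNemar test). The summits at Chro, MFS18, Pgm1, CG5098 and PNPase had no match, while those at CG8188 and lolal did. Whether the ribosomal protein gene peaks share the matrix sequence stays open, as the matrix matched 9.68% of 62 summits (4.51 to 19.5), 7.26% of their flanks and 7.06% of rank-matched promoter peaks, too few to separate. The 62 peaks were not limited to held-out arms, and some, such as that of RpL7, were among the peaks the matrix was fitted to. Recovery of DNA at very strongly transcribed promoters whatever protein is tagged also stays open as a candidate explanation, since neither transcript levels nor a control library were analysed here. The peaks may already be called against a control, which the sources used here do not spell out.

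Coding exons held 0.502% of summits against 13.8% at random. Base composition accounts for part of the gap only, because placements matched on AT content fell in coding exons in 6.96% of cases, and the lowest of 100 draws was 5.76%. A single replicate as the source is argued against by the highest share among the replicates' own top peaks, 3.88% in replicate 3, which lay below the lowest of its 100 random draws (12.5%). Lower mappability or sonication bias along genes might contribute and was not tested.

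Combined peaks of lower score often lacked support in all 3 replicates, and that score comes from the same 3 replicates pooled. The limit on the number of top peaks explains some of this, since 58.2% of the lower-scoring 1494 peaks were overlapped in all 3 replicates by a top 10000 peak, up from 19.3% with the top 2988 and against at most 2.01% in 100 random placements, but the value is between the bounds set for calling that limit sufficient or not. Replicate 3 was the one that lacked peaks most often, with 63.9% of them at that length against 94.9% and 94.5% in replicates 1 and 2. Whether the lower-scoring peaks lack the matrix sequence, which only a minority of the strongest peaks carry, cannot be told apart from a lower rate of it. The matrix matched 5.83% of their summits on held-out arms and 4.85% of flanks (exact McNemar test, p = 0.374). That p met the outcome set in advance for a lack of the sequence. The question was left open after still weaker pooled peaks were seen to exceed their flanks. Their summit share of 4.95% was, however, no higher than the 5% of flank windows that the score limit was set to pass, a limit set on other arms.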

How the results depend on the processing

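Depth is unknown here, so alternatives test settings and replicates, not depth. The overlap of replicates (39.6% to 74.7%), the promoter share (33.2% to 59.8%) and the score difference between promoter and other peaks kept their direction and their side of the threshold under all alternatives run, as did the number of gene lists past the threshold, 5 throughout. The promoter share also exceeded placements matched on AT content (13.4%), an alternative chosen after seeing the data. Support in all 3 replicates was 50.3%. It became 71.7% with the top 10000 peaks and 30.7% with a reciprocal overlap of 50%, which by construction admit more or fewer peaks, 81.3% in the 1494 highest-scoring combined peaks, and 53.9% to 66.6% when 1 replicate was left out. The score correlation of single pairs, each leaving out 1 replicate, went from 0.644 to 0.801. Arms past the threshold were 3, 4 in the 1494 highest-scoring peaks, where 3L passed as lower (ratio 0.878), and 5 with the expectation from gene count. Motifs past the threshold were 6, and 3 to 7 without 1 replicate. The search put the same 8-mer first without replicates 2 and 3 (3.06% and 2.31% of held-out summits) and another without replicate 1, which did not pass (1.45%, p = 0.0574, exact McNemar test). The 8-mer of the full list, kept in an alternative chosen after seeing the data, stayed called there (2.63%). Against promoters without a peak, centred on the TSS rather than on a summit, the direction turned for DRE (2.41%), BEAF-32 core (15.9%) and Motif 1 (0.778%), all lower at peaks, and for GAGA (1.20%), which did not pass there. The initiator was lower at peaks there and passed (8.21% against 23.4%). Summits outside ribosomal protein genes had a median position of -132 bp, so the 2 sets of windows cover unlike positions. These directions therefore do not set promoters with a peak apart from those without. Of 229 alternatives for single lists, single motifs and the chromosomes X and 4, 207 kept their call, 10 lost it, 8 gained it and 4 turned. Arm tests on dm3 were not run, since arm lengths of that build were not used here.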

Other observations

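The tests in this part used the weight matrix and gene pairs, both chosen after the peaks had been examined. Promoter summits at genes other than those of ribosomal proteins were described by peak score, in 5 equal groups of the combined list. In the strongest group, they had a median position of -160.5 bp and 9.55% of 314 lay within 50 bp of the TSS. In the weakest group the median was -103 bp and 17.0% of 224 lay within 50 bp. These positions were not tested. The weight matrix matched 13.3% of held-out summits in the strongest group (95% Wilson interval 9.69 to 17.9) against 4.17% of flanks (exact McNemar test, p = 0.00246), and 5.53% against 5.96% in the weakest group. On held-out arms it matched 7.29% of peaks away from promoters against 3.80% of their flanks (exact McNemar test, p = 0.0225), and 7.14% of promoter peaks against 5.48% (p = 0.201, exact McNemar test). The difference between both sets was not tested.

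The hypothesis that CG10274 peaks prefer promoters shared by divergent genes may be weighed with the share of promoter peaks that have protein-coding TSSs of both strands within 500 bp. It was 27.8% of 1316 peaks (95% Wilson interval 25.5 to 30.3), against a mean of 24.99% at random promoters and at most 27.8%. It lay above 99 of the 100 draws, short of the 100 that had been set in advance, so the preference stays undecided and would be small.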
